A study of Mus musculus with 14 samples.

How the data were processed

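Polyadenylated RNA of 14 macrophage samples was sequenced with a stranded mRNA library kit on a NextSeq instrument in paired 76 bp reads. Per the labels, alignment used TopHat2 and expression used Cufflinks and Cuffnorm, with no versions, options or scaling method stated. The deposited table gives FPKM, fragment counts divided by transcript length and library size and scaled between libraries by Cuffnorm, with 1 line per gene entry, its assembled locus and 1 column per library. Entries can share a locus, as 3744 of the tested entries did. The table holds 39721 entries, of which 1859 carry no gene name and 1066 name several genes. The labels name genome build mm9. Of 33853 entries naming 1 gene of GENCODE M21, 33796 overlapped the GRCm38 gene of that name and 13336 had the same start and end, so coordinates are given as GRCm38. The LPS dose was not stated.

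No counts or library totals are in the table, so absolute depth is unknown and no counting interval is given. The spacing of low values, which are multiples of 1 fragment, gave relative depth multiplied by the unknown scaling factor. This product differed by 3.07-fold between the largest and smallest library, which is not a range of depth alone, and 91 of 91 pairs of libraries lay within 0.1 log2 of the fitted values. Entries without a name took 6.33% to 17.7% of FPKM and entries naming several genes 12.1% to 15.4%.

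Groups followed the labels: PBS or Poly I:C first, then PBS or LPS, for 2 h or 6 h. Values were transformed as log2(FPKM + 1), and named entries with at least 1 FPKM in at least 2 libraries were kept, leaving 11977, of which 832 name several genes and 9586 name 1 protein-coding gene. Tested entries are called genes below. A linear model with 1 mean per group was fitted to all 14 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend, 6 residual degrees of freedom and a median prior of 3.99. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in 2-sided tests. The 11 comparisons were, at each time, Poly I:C against PBS before LPS, LPS against PBS after PBS, LPS against PBS after Poly I:C, Poly I:C against PBS before PBS, and the interaction, together with the difference of the first of these between 6 h and 2 h. Genes induced at least 2-fold by LPS alone at one time were also tested at the other.

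Before the data were examined, 31 gene lists with 580 entries were fixed, together with the comparisons, other settings to try and the rule for naming genes. The lists cover inflammatory cytokines, chemokines, interferon-stimulated genes, type I interferon and its receptors, guanylate-binding proteins, MHC class I, MHC class II, glycolysis, HIF targets, the tricarboxylic acid cycle, oxidative phosphorylation, cholesterol biosynthesis, cholesterol efflux, negative regulators and components of TLR signalling, NF-kB subunits, inflammasome, effectors, immediate-early genes, amino-acid and ER stress, resident macrophage genes, cell cycle, ribosomal proteins, 6 lists of other cell types, replication histones and mitochondrially encoded genes. Members with an entry of their own were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Member counts use the adjustment over all genes, and also one over the list alone.

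Genes were named by 3 parts of a rule: the 5 largest increases and 5 largest decreases of each comparison with a mean of at least 5 FPKM and no overlap between groups, up to 4 called members of each list, and a fixed set of inflammatory, metabolic and receptor genes. Genes named in one comparison may be given in another. The labels number replicates but pair none. As planned beforehand, no replicate term was used, and a fit with one was an alternative. Deviations of like-numbered replicates correlated at -0.19 to 0.078 over 15 pairs of groups.

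The pipeline was tested on simulated data with 200 changed genes among 11977. With 2 libraries against 2 it recovered 85% of changes of log2 1 and 100% of changes of log2 2, with 4.64% false calls. With 2 against 1 it recovered 78% and 99%, with 5.35% false calls. Changes were placed only in genes above a minimum level in the reference group, so the recovery does not cover weaker genes. Noise was drawn from the fitted variances, so the lone control was given the spread of the other groups. In the data 61.1% of genes were called for Poly I:C against PBS before LPS at 2 h, far more than were simulated. The alternatives were a pseudocount of 0.1, no filter, median-of-ratios scaling, no intensity trend, the libraries of 1 time alone, both PBS-then-PBS libraries as 1 control group, a replicate term, and leaving out each replicate. Entries naming 1 protein-coding gene alone, and list members from entries naming several, were added after the data had been seen. Groups held too few libraries for a test of other splits or of outlying libraries. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 served for annotation and plots. Unnamed loci were left out of the comparisons.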

Results

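Transcript levels were measured by RNA sequencing of polyadenylated RNA in 14 libraries of macrophages grown from the bone marrow of male C57Bl6/J mice. Cells received PBS or Poly I:C at 100 ng/mL for 24 h and then PBS or LPS for 2 h or 6 h, giving 8 groups. Poly I:C is a synthetic double-stranded RNA sensed by the receptor TLR3, and LPS is a bacterial cell wall component sensed by TLR4. Each group had 2 libraries except the PBS-then-PBS groups, with 1 library at each time. The deposited values were FPKM, whose absolute depth is unknown. Steps between low values placed the value of 1 fragment within a 3.07-fold range across libraries. Nothing in the labels says that replicates came from separate animals or cultures, so every p-value measures only the spread between these samples, which may be technical.

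Replicates of a group correlated across the 11977 tested genes at r = 0.974 to 0.988, a correlation across genes, which are not independent replicates. The lowest was the PBS-then-LPS pair at 2 h, the reference of the main comparison at that time. Its replicates lay over 2-fold apart in 306 genes, against 95 to 217 in the other groups. The first principal component held 48.3% of the variance and the second 19.6%. PBS-then-PBS libraries had the lowest scores on the first component, and Poly I:C-then-LPS libraries of both times the highest. Throughout, log2 fold changes are differences of mean log2(FPKM + 1) with their standard error, which understate the change of weakly expressed genes. FPKM values are means with SD over 2 libraries, or the value of the 1 library of a PBS-then-PBS group. Coordinates are GRCm38 and give the assembled locus, which for Ptgs2 also holds 7530420F21Rik.

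**Figure D1:**
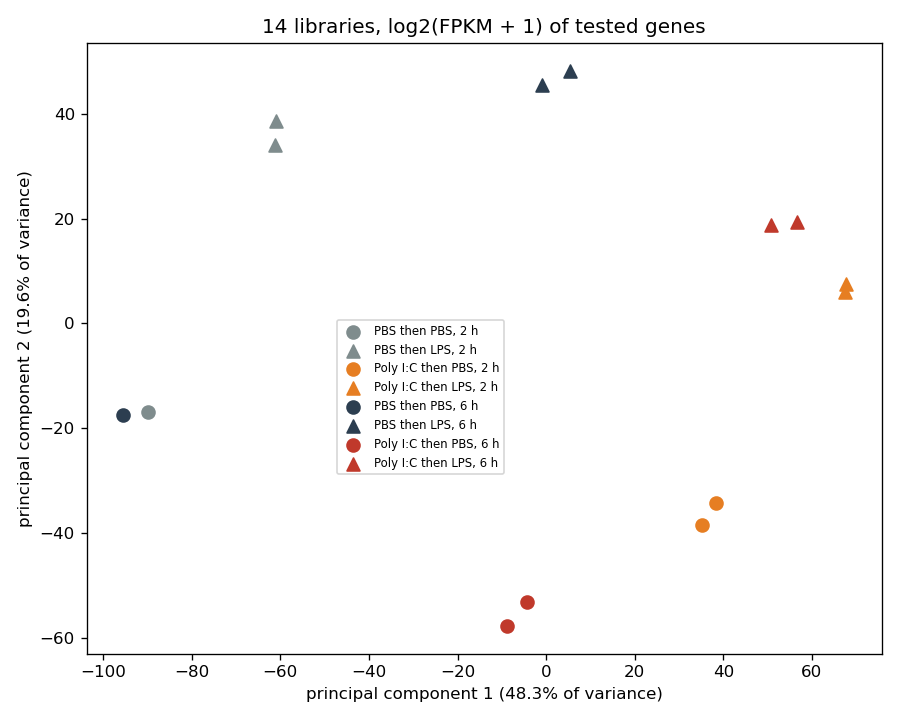
Scores of the 14 libraries on the first and second principal components of log2(FPKM + 1) over the tested genes, with circles for PBS and triangles for LPS as the later stimulus, and colours for the earlier stimulus and the time. The axes give each component's share of the variance, 48.3% and 19.6%, and both libraries of each replicated group lie close together.

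The main comparison asked how an earlier Poly I:C stimulus altered transcript levels reached after LPS. At 2 h after LPS, cells that had received Poly I:C held more inflammatory cytokine transcript than cells that had received PBS (n = 2 libraries per group). Tnf, a central inflammatory cytokine (chromosome 17, 35199381 to 35202007), stood at 5856 ± 296 FPKM after Poly I:C then LPS and 659 ± 49.7 FPKM after PBS then LPS, a log2 fold change of 3.15 ± 0.48 (limma adjusted p = 2.37e-04), with both primed libraries above both unprimed ones. Il6 (chromosome 5, 30013161 to 30019968) stood at 359 ± 51.5 against 26.7 ± 9.76 FPKM, and Ptgs2, which encodes the prostaglandin-forming enzyme COX-2 (chromosome 1, 150074873 to 150108236), at 1039.8 ± 39.9 against 8.08 ± 1.81 FPKM. Interferon-stimulated and antigen presentation genes were higher as well, whereas most genes of cell division and cholesterol synthesis were lower. Most listed genes of glycolysis and ribosomal proteins were lower too, but these lists lost their camera call (adjusted p = 0.196 and 0.334 with an estimated correlation), as did the inflammatory cytokines, the interferon-stimulated genes and MHC class I (adjusted p = 0.184, 0.173 and 0.173).

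Of the inflammatory cytokines at 2 h, 15 of 20 tested members were higher and 1 lower (15 and 3 adjusted over the list alone). The median was 2.00 (camera adjusted p = 2.31e-04, and adjusted p = 0.184 with an estimated correlation). Il23a changed by 5.87 ± 0.18, Tnfsf10 by 4.86 ± 0.23, Il1a by 4.18 ± 0.56, Il6 by 3.74 ± 0.46 and Il1b by 2.02 ± 0.35. Il12b, the p40 chain of IL-12, did not pass the test, at -0.59 ± 0.25, except with the 2 h libraries alone, at the same value (adjusted p = 0.0295). Among chemokines, 12 of 18 tested members were higher and 2 lower (13 and 2 adjusted over the list alone). The median was 1.60 (camera adjusted p = 0.00312, and adjusted p = 0.334 with an estimated correlation). Ccl5 was higher by 4.84 and Cxcl9 by 5.17, while Cxcl10 stood at 2309 ± 4.21 and 2295 ± 410.0 FPKM, a difference smaller than the replicate error (limma adjusted p = 0.939). Among effectors of inflammation and defence, 17 of 21 tested members were higher and 1 lower (17 and 2 adjusted over the list alone). The median was 1.55 (camera adjusted p = 2.92e-05, and adjusted p = 0.163 with an estimated correlation). Ptgs2 changed by 6.86 ± 0.35 and Nos2, the inducible nitric oxide synthase, by 3.84 ± 0.29. Irg1, now called Acod1, which makes itaconate, was higher by 2.51. The anti-inflammatory cytokine Il10 was higher by 2.13, and Socs3, an inhibitor of cytokine receptor signalling, did not pass at -0.17 ± 0.53.

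Interferon-stimulated genes, which cells switch on in response to interferon, were nearly all higher at 2 h: 27 of 28 tested members were higher and 0 lower (27 and 0 adjusted over the list alone). The median was 3.27 (camera adjusted p = 2.04e-14, and adjusted p = 0.173 with an estimated correlation). Isg20 changed by 6.83 ± 0.26, Ifi44 by 6.75 ± 0.11, Irf7 by 5.50 ± 0.25 and Isg15 by 3.61 ± 0.23. All tested guanylate-binding proteins and related GTPases passed: 9 of 9 tested members were higher and 0 lower (9 and 0 adjusted over the list alone). The median was 3.87 (camera adjusted p = 1.24e-06, and adjusted p = 0.083 with an estimated correlation). MHC class I presentation genes followed the same direction: 12 of 12 tested members were higher and 0 lower (12 and 0 adjusted over the list alone). The median was 3.01 (camera adjusted p = 1.35e-07, and adjusted p = 0.173 with an estimated correlation). For MHC class II and costimulation, 13 of 14 tested members were higher and 0 lower (13 and 0 adjusted over the list alone). The median was 1.87 (camera adjusted p = 8.04e-07, and adjusted p = 0.0456 with an estimated correlation). H2-Aa changed by 5.90 ± 0.18 and H2-Ab1 by 5.45 ± 0.12. Of the type I interferon and receptor genes, 5 of 6 tested members were higher and 0 lower (5 and 0 adjusted over the list alone). The median was 1.02 (camera adjusted p = 0.0207, and adjusted p = 0.173 with an estimated correlation). Ifnb1 changed by 2.24 ± 0.36 and the kinase gene Tyk2 by 2.37 ± 0.11. The inflammasome and cell death list gave 13 higher and 1 lower of 15 (13 and 1 adjusted over the list alone, camera adjusted p = 1.21e-05, and adjusted p = 0.173 with an estimated correlation). Pyhin1 was higher by 5.21 and Mlkl, the effector of necroptosis, by 3.68. The largest increases among genes averaging at least 5 FPKM in either group were Ms4a4c (chromosome 19, 11404487 to 11427246) at 8.90 ± 0.21, Slfn4 at 8.79 ± 0.29, Ly6a at 7.54 ± 0.16, Slfn1 at 7.17 ± 0.24 and H2-Q6 at 7.14 ± 0.23. Schlafen genes and H2-Q genes have near-identical copies, so their values are uncertain where reads could be shared.

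Lower at 2 h with Poly I:C were most cell cycle genes: 1 of 23 tested members was higher and 21 lower (1 and 21 adjusted over the list alone). The median was -3.12 (camera adjusted p = 2.68e-11, and adjusted p = 0.0456 with an estimated correlation). Birc5 fell by 5.09 on the log2 scale, Ccnb2 by 4.68 and Cdk1 by 4.27. The largest decreases by rule were Igfbp4 at -5.70 ± 0.18, Ube2c at -5.68 ± 0.31, the mannose receptor gene Mrc1 (chromosome 2, 14229306 to 14332063) at -5.51 ± 0.15, Cdca3 at -5.32 ± 0.19 and a merged locus naming Gm23634 and Stmn1 at -5.19 ± 0.21. Cholesterol biosynthesis genes were lower: 0 of 21 tested members were higher and 20 lower (0 and 21 adjusted over the list alone). The median was -2.12 (camera adjusted p = 1.32e-10, and adjusted p = 0.00816 with an estimated correlation). Fdps changed by -4.88 ± 0.20 and Cyp51 by -3.09 ± 0.18. The glycolysis list, including lactate export, gave 2 higher and 15 lower of 20 (2 and 16 adjusted over the list alone) and a median of -0.95 (camera adjusted p = 1.65e-04, and adjusted p = 0.196 with an estimated correlation). Aldoc changed by -4.01 ± 0.31, Gapdh by -1.55 ± 0.14, Ldha by -0.59 ± 0.14 and Hk2, a hexokinase, by -0.75 ± 0.14. The glucose transporter gene Slc2a1 was higher by 0.58, and the lactate exporter gene Slc16a3 did not pass at -0.03 ± 0.14. For the tricarboxylic acid cycle, 1 of 25 tested members was higher and 18 lower (1 and 18 adjusted over the list alone). The median was -0.56 (camera adjusted p = 5.17e-05, and adjusted p = 0.13 with an estimated correlation). Idh2 changed by -3.52 ± 0.17. Nuclear-encoded respiratory chain genes gave 1 higher and 18 lower of 28 (1 and 18 adjusted over the list alone, camera adjusted p = 5.01e-04, and adjusted p = 0.47 with an estimated correlation). Ribosomal protein genes gave 1 higher and 17 lower of 19 (1 and 17 adjusted over the list alone, camera adjusted p = 1.15e-05, and adjusted p = 0.334 with an estimated correlation). Rpl3 changed by -2.85 ± 0.14. Hif1a, a hypoxia-response regulator, was higher by 1.26. The list of its targets outside glycolysis, which counts Hif1a itself as a member, went both ways, 7 higher and 4 lower of 18 (7 and 4 adjusted over the list alone, camera adjusted p = 0.713, and adjusted p = 0.711 with an estimated correlation).

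Across all tested genes at 2 h, 3905 were higher and 3408 lower with Poly I:C, of which 2132 and 1654 by at least 2-fold, and the median of all genes was 0.054. The receptor gene Tlr3 changed by 3.57 ± 0.15 and Tlr4 by 1.10 ± 0.23, in a pathway list that gave 18 higher and 1 lower of 26 (18 and 1 adjusted over the list alone, camera adjusted p = 2.31e-04, and adjusted p = 0.197 with an estimated correlation). Arg1, an arginase linked to alternative activation, did not pass at -0.09 ± 0.14. Its level was 0 and 0.131 FPKM after PBS then LPS and 0 in both libraries after Poly I:C then LPS, so no change could be seen. A locus of merged mitochondrial genes held 0.645% and 0.735% of named FPKM in the Poly I:C-then-LPS libraries and 1.52% and 2.82% in the PBS-then-LPS libraries. The stromal marker Dcn was higher by 3.13 in a stromal list with 4 higher and 0 lower of 8 (4 and 0 adjusted over the list alone), of which 3 did not pass without Poly I:C-then-LPS replicate 1.

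**Figure D2:**
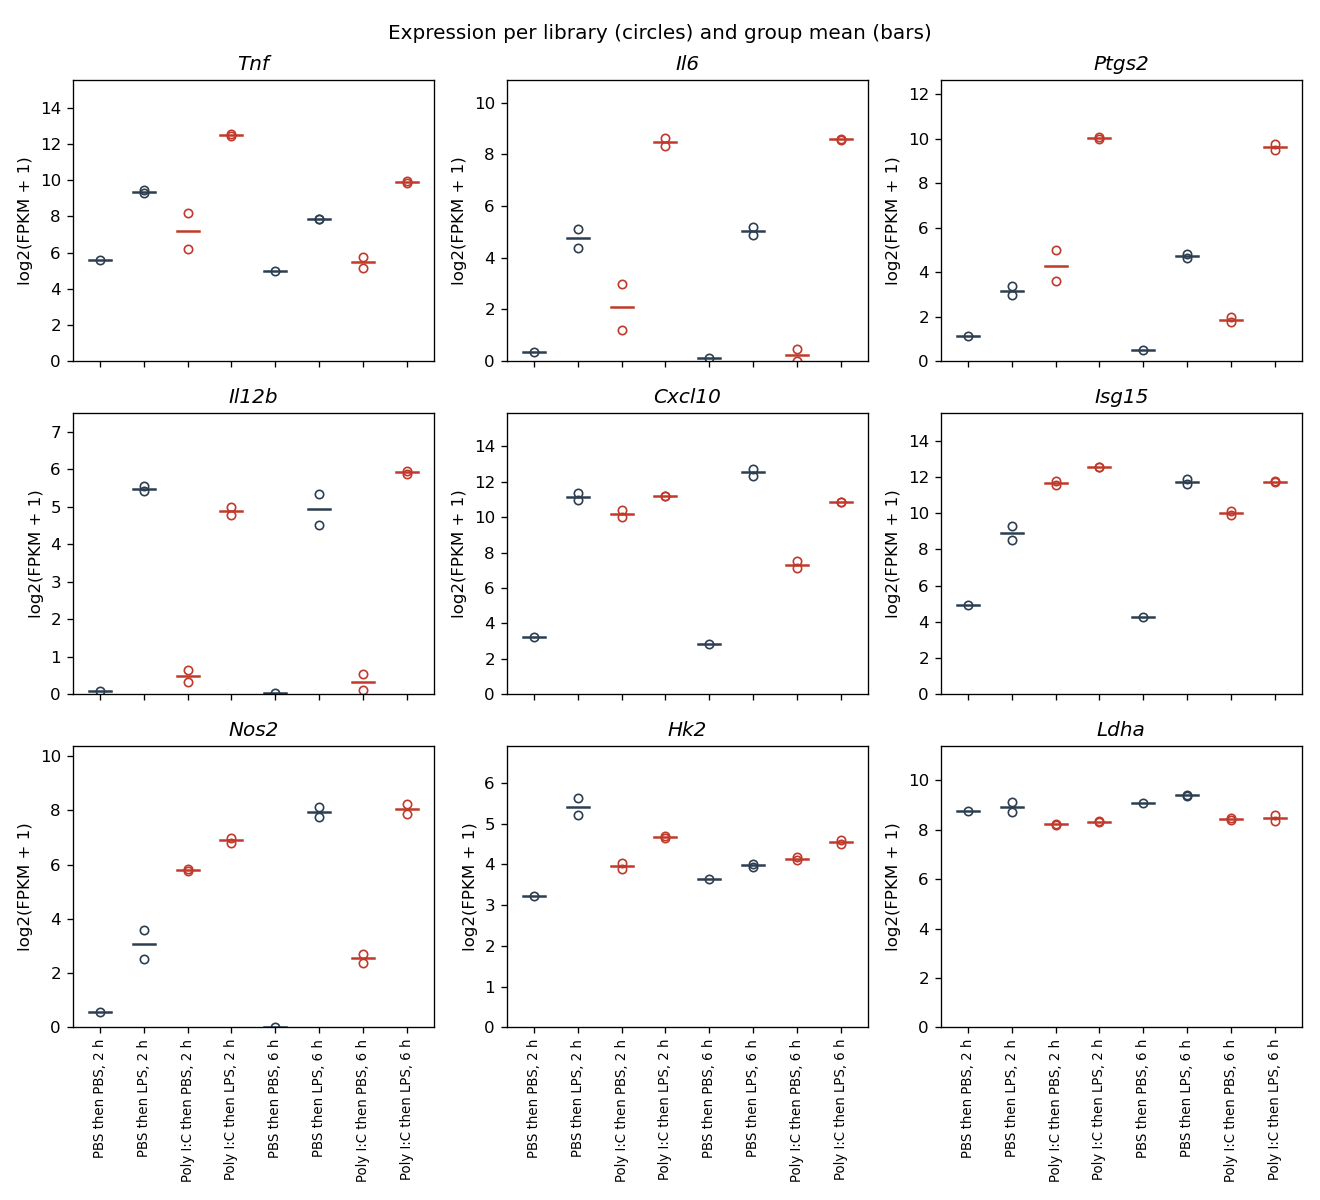
Expression of 9 genes in each library (circles, log2(FPKM + 1)) with group means (bars), dark for PBS and red for Poly I:C as the earlier stimulus. At both times Tnf, Il6 and Ptgs2 lie higher after Poly I:C then LPS than after PBS then LPS, while Cxcl10 lies lower at 6 h and Isg15 overlaps at 6 h.

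At 6 h after LPS, most inflammatory cytokine genes were again higher with Poly I:C, while 2 of 28 interferon-stimulated genes were higher and 11 lower (n = 2 libraries per group). Tnf stood at 951 ± 49.6 FPKM after Poly I:C then LPS and 227 ± 0.277 FPKM after PBS then LPS, a log2 fold change of 2.06 ± 0.48 (limma adjusted p = 0.00498), again with both libraries above both others. Il6 changed by 3.57 ± 0.46, Il1b by 2.11 ± 0.35 and Ptgs2 by 4.90 ± 0.35. The neutrophil-attracting chemokine genes Cxcl1 (chromosome 5, 90891241 to 90893115) and Cxcl3 were higher by 6.23 ± 0.33 and 5.81 ± 0.36. Cxcl10, an interferon-induced chemokine gene, changed by -1.67 ± 0.20, at 1855 ± 6.60 against 5968 ± 1165 FPKM.

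Of the inflammatory cytokines at 6 h, 15 of 20 tested members were higher and 4 lower (15 and 4 adjusted over the list alone). The median was 1.07 (camera adjusted p = 0.00454, and adjusted p = 0.459 with an estimated correlation). Il23a was higher by 3.81 and Csf2 by 3.50. Il12b was higher by 0.98 (limma adjusted p = 0.00912), a call lost without PBS-then-LPS replicate 2 (0.56), without Poly I:C-then-LPS replicate 2 (0.94) and with a pseudocount of 0.1 (1.00). Chemokines went both ways, 6 higher and 7 lower of 18 (6 and 7 adjusted over the list alone, camera adjusted p = 0.978, and adjusted p = 0.99 with an estimated correlation). Ccl7 changed by -2.94 and Ccl5 by 1.29. Of the interferon-stimulated genes, 2 of 28 tested members were higher and 11 lower (2 and 11 adjusted over the list alone). The median was -0.35 (camera adjusted p = 0.0757, and adjusted p = 0.834 with an estimated correlation). Rsad2, encoding the antiviral protein viperin, changed by -1.86 ± 0.15 and Cmpk2 by -1.82 ± 0.21, while Isg15 stood at 3418 ± 34.2 and 3419 ± 488 FPKM (limma adjusted p = 0.986) and Irf7 did not pass at 0.59 ± 0.25, except with the 6 h libraries alone, at the same value (adjusted p = 0.0193). MHC class II and costimulation genes gave 12 higher and 1 lower of 14 (12 and 1 adjusted over the list alone, camera adjusted p = 1.08e-06, and adjusted p = 0.0479 with an estimated correlation). H2-Aa changed by 4.98 ± 0.18. MHC class I genes gave 7 higher and 1 lower of 12 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00228, and adjusted p = 0.516 with an estimated correlation). H2-Q7 changed by 6.24 ± 0.27 and H2-Q6 by 5.98 ± 0.23. NF-kB subunit genes gave 4 higher and 0 lower of 4 (4 and 0 adjusted over the list alone, camera adjusted p = 0.00941, and adjusted p = 0.459 with an estimated correlation). Nos2, Il10 and Socs3 did not pass, at 0.12 ± 0.29, -0.29 ± 0.31 and -0.08 ± 0.53, and Ifnb1 was higher by 2.15.

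Glycolysis genes were mostly lower with Poly I:C at 6 h too: 1 of 20 tested members was higher and 17 lower (1 and 17 adjusted over the list alone). The median was -1.12 (camera adjusted p = 9.49e-07, and adjusted p = 0.214 with an estimated correlation). Pgk1 changed by -1.66 ± 0.13, Pgam1 by -1.49 ± 0.13, Ldha by -0.90 ± 0.14 and Slc16a3 by -1.08 ± 0.14. Resident and alternative macrophage genes were mostly lower, 0 higher and 19 lower of 22 (0 and 20 adjusted over the list alone, camera adjusted p = 2.77e-09, and adjusted p = 0.0101 with an estimated correlation). Mrc1 changed by -4.68 ± 0.15 and the fractalkine receptor gene Cx3cr1 by -4.28 ± 0.23. Arg1 changed by -2.52 ± 0.14, Tlr4 by -1.34 ± 0.23 and Tlr3 by -1.15 ± 0.15. Levels of Arg1 were low, at 4.87 and 4.62 FPKM after PBS then LPS and 0 in both libraries after Poly I:C then LPS. Cholesterol biosynthesis genes gave 0 higher and 17 lower of 21 (0 and 19 adjusted over the list alone, camera adjusted p = 2.09e-07, and adjusted p = 0.0113 with an estimated correlation). Cell cycle genes gave 1 higher and 19 lower of 23 (1 and 20 adjusted over the list alone, camera adjusted p = 1.17e-07, and adjusted p = 0.0635 with an estimated correlation). The largest decreases by rule also held the cyclin gene Ccnd1 at -5.49 ± 0.24 and Cbr2 at -5.11 ± 0.40. Tricarboxylic acid cycle genes gave 1 higher and 16 lower of 25 (1 and 16 adjusted over the list alone, camera adjusted p = 0.00113, and adjusted p = 0.232 with an estimated correlation). Respiratory chain genes gave 0 higher and 15 lower of 28 (0 and 16 adjusted over the list alone, camera adjusted p = 0.00113, and adjusted p = 0.733 with an estimated correlation). Ribosomal protein genes gave 1 higher and 14 lower of 19 (1 and 15 adjusted over the list alone, camera adjusted p = 0.00329, and adjusted p = 0.733 with an estimated correlation).

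In all, 2841 genes were higher and 3099 lower at 6 h, of which 1099 and 1377 by at least 2-fold. Between the times, 1492 genes were higher at both where independent lists would share 926, and 1584 were lower at both where they would share 882. Another 665 were higher at 2 h and lower at 6 h, and 469 the reverse. The rule also named the short RNAs DLEU2_5 at 6.58 ± 2.49, Gm23487 at -6.41 ± 0.24 and mmu-mir-6363 at -5.10 ± 1.17. Hk2 (0.57 ± 0.14), Slc2a1 (-0.33 ± 0.10), Irg1 (-0.50 ± 0.17) and DLEU2_5 passed, but not in every fit that left out a library. Hk2 lost its call without PBS-then-LPS replicate 2 (0.53) or Poly I:C-then-LPS replicate 1 (0.51), and the other 3 without any of the 4 libraries, at -0.36 to -0.31, -0.58 to -0.43 and 6.14 to 7.02. Irg1 and DLEU2_5 also did not pass without the filter, nor DLEU2_5 with a replicate term (adjusted p = 0.0655) or without the intensity trend (adjusted p = 0.0542), at the same value.

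The test of the difference between times asked which Poly I:C effects on the LPS level differed at 6 h from 2 h (n = 2 libraries per group). The values are differences of this effect, not levels. For interferon-stimulated genes the effect was lower at 6 h: 0 of 28 tested members were higher and 27 lower (0 and 28 adjusted over the list alone). The median was -3.75 (camera adjusted p = 1.39e-18, and adjusted p = 0.16 with an estimated correlation). The difference was -7.84 ± 0.29 for Ms4a4c, -6.50 ± 0.36 for Isg20, -4.91 ± 0.36 for Irf7 and -4.71 ± 0.22 for Tlr3. Ms4a4c after PBS then LPS rose from 5.18 FPKM at 2 h to 846 at 6 h. After Poly I:C then LPS it stood at 2902 and 1739 FPKM. Inflammatory cytokines gave 1 higher and 5 lower of 20 (1 and 5 adjusted over the list alone, camera adjusted p = 0.223, and adjusted p = 0.621 with an estimated correlation). Tnf and Il6 did not pass, at -1.09 ± 0.67 and -0.17 ± 0.65. The effect on Cxcl1 and Cxcl3 was higher by 2.61 ± 0.47 and 3.75 ± 0.51. MHC class I genes gave 0 higher and 11 lower of 12 (0 and 11 adjusted over the list alone, camera adjusted p = 6.56e-06, and adjusted p = 0.279 with an estimated correlation). The inflammasome and cell death list gave 0 higher and 14 lower of 15 (0 and 14 adjusted over the list alone, camera adjusted p = 3.08e-07, and adjusted p = 0.16 with an estimated correlation). Cell cycle genes gave 15 higher and 1 lower of 23 (15 and 1 adjusted over the list alone, camera adjusted p = 1.14e-05, and adjusted p = 0.143 with an estimated correlation). The effect on the GTPase Rnd1 was higher by 4.87 ± 0.37. In all, the Poly I:C effect was higher at 6 h than at 2 h for 2282 genes and lower for 3030. Short RNAs again came up by rule, with mmu-mir-1957b at 6.00 ± 1.02, Gm25777 at 5.93 ± 1.73 and adapt33_3 at 5.87 ± 0.98, of which Gm25777 lost its call without PBS-then-LPS 2 h replicate 2 (5.58), PBS-then-LPS 6 h replicate 2 (5.93) or Poly I:C-then-LPS 6 h replicate 1 (4.32), and without the filter. Merged loci naming Slc28a2 with Gm14086 and 2010002M12Rik with Gm14446 changed by -6.73 ± 0.29 and -6.46 ± 0.29.

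**Figure D3:**
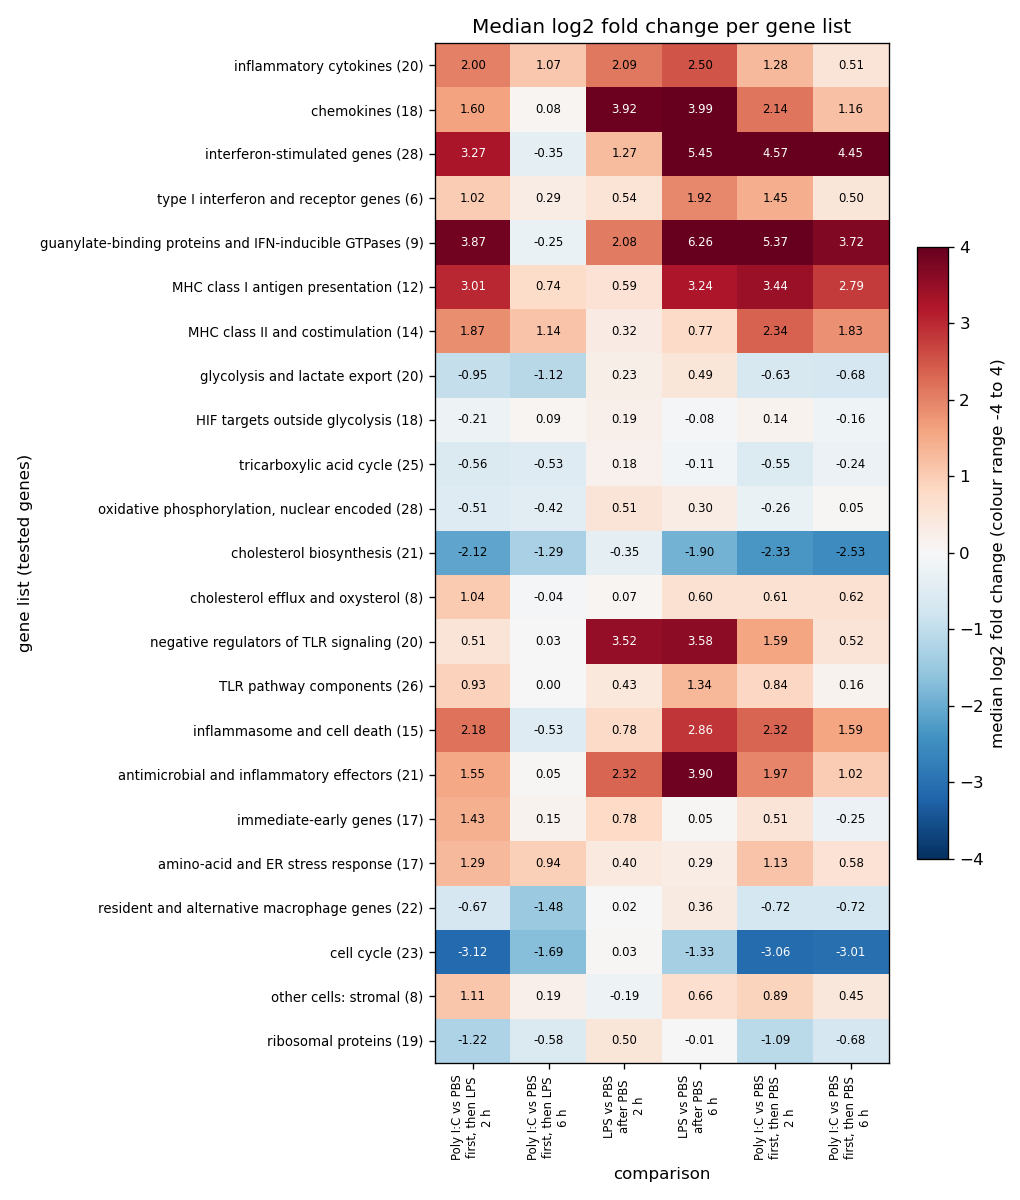
Median log2 fold change of each gene list with at least 5 tested genes (lines, number tested in parentheses) in 6 comparisons (columns), red for higher and blue for lower, with the values printed. Interferon-stimulated genes have a median of 3.27 at 2 h and -0.35 at 6 h for Poly I:C against PBS before LPS, and glycolysis genes -0.95 and -1.12.

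LPS alone, after PBS, gave the reference response (2 LPS libraries against 1 control at each time, the lone control being assumed to vary like the other groups). At 2 h Cxcl10 changed by 7.93 ± 0.25, from 8.37 to 2295 ± 410.0 FPKM. Il1b was higher by 7.28 ± 0.43, Socs3 by 7.48 ± 0.64, Tnfsf9 by 6.70 ± 1.02, Irg1 by 6.66 ± 0.21 and Tnf by 3.79 ± 0.58. Chemokines gave 16 higher and 0 lower of 18 (17 and 0 adjusted over the list alone, camera adjusted p = 1.33e-17, and adjusted p = 0.0578 with an estimated correlation). Negative regulators of TLR signalling gave 19 higher and 0 lower of 20 (19 and 0 adjusted over the list alone, camera adjusted p = 6.17e-22, and adjusted p = 0.0578 with an estimated correlation). Interferon-stimulated genes gave 21 higher and 0 lower of 28 (24 and 0 adjusted over the list alone, camera adjusted p = 1.90e-18, and adjusted p = 0.117 with an estimated correlation). The phosphatase gene Dusp6 changed by -4.33 ± 0.24, Hhex by -3.78 ± 0.31 and Plk3 by -3.68 ± 0.17, and the short RNAs Gm24853 and n-R5s197 by -3.98 ± 0.87 and -3.20 ± 0.90. The latter did not pass without either LPS replicate (-3.20 each) or with both controls as 1 group (-1.60), and neither passed without the filter or with the 2 h libraries alone. The decrease of n-R5s197 rests on the level in the lone 2 h control library. Hk2 was higher by 2.19 ± 0.18 in a glycolysis list with 5 higher and 1 lower of 20 (5 and 1 adjusted over the list alone, camera adjusted p = 0.00975, and adjusted p = 0.409 with an estimated correlation). In all, 1134 genes were higher and 765 lower at 2 h. Without PBS-then-LPS replicate 2 these counts were 2296 and 1407, with the 2 h libraries alone 747 and 429, and with both PBS-then-PBS libraries as 1 control group 1720 and 1153.

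By 6 h of LPS alone all tested interferon-stimulated genes were higher: 28 of 28 tested members were higher and 0 lower (28 and 0 adjusted over the list alone). The median was 5.45 (camera adjusted p = 8.40e-26, and adjusted p = 0.0722 with an estimated correlation). Ccl5 changed by 10.53 ± 0.31, the acute-phase gene Saa3 by 10.01 ± 0.54, Cxcl10 by 9.71 ± 0.25, Rsad2 by 9.19 ± 0.19 and Irg1 by 8.94 ± 0.21. Guanylate-binding proteins and related GTPases gave 7 higher and 0 lower of 9 (7 and 0 adjusted over the list alone, camera adjusted p = 7.11e-08, and adjusted p = 0.0722 with an estimated correlation). Inflammatory cytokines gave 15 higher and 0 lower of 20 (15 and 0 adjusted over the list alone, camera adjusted p = 1.75e-07, and adjusted p = 0.0722 with an estimated correlation). Nos2 was higher by 7.91 ± 0.36, and Slc2a1 by 1.37 ± 0.12 in a glycolysis list with 10 higher and 1 lower of 20 (11 and 1 adjusted over the list alone, camera adjusted p = 0.00311, and adjusted p = 0.28 with an estimated correlation). Cholesterol biosynthesis genes were lower, 0 higher and 19 lower of 21 (0 and 20 adjusted over the list alone, camera adjusted p = 3.11e-11, and adjusted p = 0.00714 with an estimated correlation). Sqle changed by -3.44 ± 0.16. Cell cycle genes gave 0 higher and 17 lower of 23 (0 and 17 adjusted over the list alone, camera adjusted p = 1.32e-08, and adjusted p = 0.0722 with an estimated correlation). The replication gene Mcm2 changed by -3.58 ± 0.18. Plau changed by -4.52 ± 0.27 and the chemokine receptor gene Cxcr4 by -4.37 ± 0.25. Short RNAs mt-Ty, Gm22077 and Mir7-1 had wide errors, at -8.70 ± 2.36, -5.13 ± 1.53 and -4.56 ± 1.34, and the latter pair lost their calls, at the same values, without either LPS replicate. With both PBS-then-PBS libraries as 1 control group all 3 lost their calls, at -4.35, -2.56 and -2.28, as they did without the filter, and mt-Ty also with the 6 h libraries alone. The decreases of these short RNAs rest on the level in the lone 6 h control library. In all, 2738 genes were higher and 2464 lower.

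LPS in cells that had first received Poly I:C was compared with PBS in such cells (n = 2 libraries per group). At 2 h Cxcl1 changed by 8.08 ± 0.33, Cxcl2 by 7.14 ± 0.72, Il1b by 6.56 ± 0.35, Il1a by 6.45 ± 0.56 and Il6 by 6.38 ± 0.46. Inflammatory cytokines gave 16 higher and 0 lower of 20 (17 and 0 adjusted over the list alone, camera adjusted p = 1.83e-13, and adjusted p = 0.0834 with an estimated correlation). Immediate-early genes gave 13 higher and 0 lower of 17 (13 and 0 adjusted over the list alone, camera adjusted p = 3.42e-08, and adjusted p = 0.135 with an estimated correlation). Interferon-stimulated genes gave 7 higher and 0 lower of 28 (9 and 0 adjusted over the list alone, camera adjusted p = 0.00223, and adjusted p = 0.589 with an estimated correlation). Ccl5, at 26213 ± 1053 FPKM with PBS and 38626 ± 958 with LPS, did not pass (limma adjusted p = 0.147). Txnip, a regulator of glucose uptake, changed by -3.65 ± 0.21, and the short RNAs Gm23100, mmu-mir-6363, Gm25541 and Gm25960 by -4.46 ± 1.12, -4.43 ± 1.17, -4.05 ± 0.34 and -3.19 ± 0.75. Of these, Gm23100, mmu-mir-6363 and Gm25960 did not pass without Poly I:C-then-PBS replicate 2 (-3.96, -3.58 and -2.91) without either LPS replicate (-4.46, -4.43 and -3.19) or without the filter, and the latter pair also not with the 2 h libraries alone. In all, 1681 genes were higher and 1044 lower. Leaving out any 1 of the 4 libraries gave 1094 to 1246 higher and 449 to 588 lower, lowest without Poly I:C-then-PBS replicate 2 in both directions, and the 2 h libraries alone gave 609 lower.

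At 6 h after Poly I:C, the largest increases by rule were in cytokine genes, Ptgs2 and Socs3. Il1b changed by 9.05 ± 0.35, Il6 by 8.35 ± 0.46, Il1a by 7.88 ± 0.56, Ptgs2 by 7.79 ± 0.35 and Socs3 by 7.55 ± 0.53. Inflammatory cytokines gave 19 higher and 0 lower of 20 (19 and 0 adjusted over the list alone, camera adjusted p = 9.67e-12, and adjusted p = 0.115 with an estimated correlation). Interferon-stimulated genes gave 25 higher and 0 lower of 28 (26 and 0 adjusted over the list alone, camera adjusted p = 6.45e-10, and adjusted p = 0.197 with an estimated correlation). Mx2 changed by 1.83 ± 0.25. The largest decreases were Cd300lb at -5.02 ± 0.20, Cxcr4 at -4.70 ± 0.20, Tmem37 at -4.69 ± 0.23, Susd3 at -4.66 ± 0.17 and Cebpa, a myeloid transcription factor gene, at -4.38 ± 0.16. In all, 2595 genes were higher and 2660 lower.

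Poly I:C alone, followed by PBS, left a broad change that was measured 2 h and 6 h into the later PBS (2 Poly I:C libraries against 1 control at each time). At 2 h Ccl5 changed by 9.91 ± 0.31, from 26.3 to 26213 ± 1053 FPKM. Slfn4 was higher by 8.52 ± 0.35, Ms4a4c by 8.32 ± 0.25, AW112010 by 8.28 ± 0.32 and the merged locus of 2010002M12Rik and Gm14446 by 8.83 ± 0.25. All tested interferon-stimulated genes passed at 2 h: 28 of 28 tested members were higher and 0 lower (28 and 0 adjusted over the list alone). The median was 4.57 (camera adjusted p = 3.39e-23, and adjusted p = 0.0829 with an estimated correlation). Guanylate-binding proteins gave 9 higher and 0 lower of 9 (9 and 0 adjusted over the list alone, camera adjusted p = 1.53e-08, and adjusted p = 0.0444 with an estimated correlation). MHC class II genes gave 12 higher and 0 lower of 14 (12 and 0 adjusted over the list alone, camera adjusted p = 3.14e-07, and adjusted p = 0.0383 with an estimated correlation). Lower were Igfbp4 at -6.05 ± 0.22, Mrc1 at -6.03 ± 0.19, Slc9a9 at -5.18 ± 0.27, the merged locus of Stmn1 at -5.10 ± 0.26 and Fdps at -4.84 ± 0.25. Cholesterol biosynthesis gave 0 higher and 20 lower of 21 (0 and 21 adjusted over the list alone, camera adjusted p = 3.40e-13, and adjusted p = 0.00433 with an estimated correlation). Cell cycle gave 1 higher and 22 lower of 23 (1 and 22 adjusted over the list alone, camera adjusted p = 5.67e-14, and adjusted p = 0.0292 with an estimated correlation). Glycolysis gave 4 higher and 13 lower of 20 (5 and 13 adjusted over the list alone, camera adjusted p = 0.0176, and adjusted p = 0.363 with an estimated correlation). The mitochondrial locus held 0.754% and 0.925% of named FPKM in the Poly I:C libraries against 2.45% in the control. In all, 2982 genes were higher and 2681 lower. Tnf, at 285 and 71.5 FPKM in the replicates, was higher by 1.60, but without Poly I:C-then-PBS replicate 1 the change was 0.61 and did not pass, and Il6 likewise moved from 1.76 to 0.87. Neither passed without the filter or with the 2 h libraries alone.

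At 6 h without LPS, interferon-stimulated genes were higher with Poly I:C: 28 of 28 tested members were higher and 0 lower (28 and 0 adjusted over the list alone). The median was 4.45 (camera adjusted p = 4.25e-28, and adjusted p = 0.0853 with an estimated correlation). Ccl5 changed by 11.24 ± 0.31, H2-Q7 by 8.87 ± 0.33, Ly6a by 8.57 ± 0.19, H2-Q6 by 8.55 ± 0.28 and Ms4a4c by 8.49 ± 0.25. Cytokines gave 7 higher and 0 lower of 20 (7 and 0 adjusted over the list alone, camera adjusted p = 0.0265, and adjusted p = 0.387 with an estimated correlation). Tnf and Il6 did not pass, at 0.51 ± 0.58 and 0.13 ± 0.57. Cell cycle genes gave 0 higher and 23 lower of 23 (0 and 23 adjusted over the list alone, camera adjusted p = 8.39e-22, and adjusted p = 0.00892 with an estimated correlation). Cholesterol biosynthesis gave 0 higher and 20 lower of 21 (0 and 20 adjusted over the list alone, camera adjusted p = 1.81e-19, and adjusted p = 0.00138 with an estimated correlation). Glycolysis gave 3 higher and 13 lower of 20 (4 and 13 adjusted over the list alone, camera adjusted p = 9.15e-04, and adjusted p = 0.288 with an estimated correlation). The mitochondrial locus held 0.895% and 0.379% of named FPKM in the Poly I:C libraries against 2.78% in the control. Igfbp4 changed by -5.57 ± 0.22 and Mrc1 by -5.33 ± 0.19, and the short RNAs mt-Ty and Gm22077 by -8.70 ± 2.36 and -5.13 ± 1.53, which did not pass without either Poly I:C replicate, at the same values, with both controls as 1 group (-4.35 and -2.56) or without the filter, nor mt-Ty with the 6 h libraries alone. The mt-Ty and Gm22077 values equal those for LPS alone at 6 h and rest on the same lone control library. In all, 2204 genes were higher and 1924 lower.

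The interaction asked whether the LPS effect itself, relative to PBS, differed after Poly I:C, with 1 control library at each time and 2 libraries in each other group. A positive value means an LPS effect that was more positive, or less negative, after Poly I:C than after PBS. At 2 h the interaction was 5.73 ± 0.29 for Il23a and 3.67 ± 0.56 for Ptgs2, which LPS raised more after Poly I:C, and 3.92 ± 0.34 for Nr4a1. It was 4.39 ± 0.22 for Plk3 and 4.27 ± 0.31 for Dusp6, which LPS lowered after PBS by -3.68 ± 0.17 and -4.33 ± 0.24 and which stood at 0.71 ± 0.14 and -0.06 ± 0.20 after Poly I:C. It was negative for Cxcl10 at -6.95 ± 0.32, Ifit1 at -5.52 ± 0.26, Mx2 at -5.39 ± 0.39, Ccl5 at -5.07 ± 0.40 and Rnd1 at -5.07 ± 0.41. Tnf and Il6 did not pass at 2 h, at 1.55 ± 0.75 and 1.98 ± 0.73, but both passed without Poly I:C-then-PBS replicate 1, at 2.54 and 2.86. Interferon-stimulated genes gave 0 higher and 12 lower of 28 (0 and 15 adjusted over the list alone, camera adjusted p = 4.55e-18, and adjusted p = 0.218 with an estimated correlation). Immediate-early genes gave 7 higher and 0 lower of 17 (8 and 1 adjusted over the list alone, camera adjusted p = 2.25e-07, and adjusted p = 0.218 with an estimated correlation). The short RNA Gm25534 came up by rule at 4.12 ± 0.99 and passed in 1 of 6 fits that left out a library, that without PBS-then-LPS replicate 2, and neither without the filter nor with a pseudocount of 0.1. In all, the interaction was positive for 302 genes and negative for 212, and without PBS-then-LPS replicate 2 for 836 and 801. The LPS effect was larger in size after Poly I:C for 202 of the positive and 28 of the negative genes, and smaller in size for 100 and 184. The positive genes numbered 146 without Poly I:C-then-PBS replicate 2 and 182 and 147 without Poly I:C-then-LPS replicates 1 and 2, and the negative genes 137 and 129 without the latter pair. The 2 h libraries alone gave 109 and 86, and a pseudocount of 0.1 gave 184 positive, and Ptgs2 did not pass with the 2 h libraries alone, at the same value.

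At 6 h the interaction was negative for all tested interferon-stimulated genes: 0 of 28 tested members were higher and 28 lower (0 and 28 adjusted over the list alone). The median was -4.45 (camera adjusted p = 6.73e-29, and adjusted p = 0.0967 with an estimated correlation). Among single genes the interaction was -9.95 ± 0.40 for Ccl5, -7.44 ± 0.24 for Rsad2, -7.43 ± 0.27 for Gbp2 and -7.43 ± 0.33 for Ms4a4c. For the merged locus of 2010002M12Rik and Gm14446 it was -7.50 ± 0.32. These are differences of LPS effects and not falls in level. Poly I:C alone had already raised all 28 list members at 6 h, and LPS after Poly I:C still raised most of them. After Poly I:C, Ccl5 stood at 17464 ± 1130 FPKM with PBS and 26049 ± 886 with LPS (limma adjusted p = 0.0917). The interaction was positive for Cxcl1 at 5.79 ± 0.53, Cxcl2 at 5.45 ± 1.13, Cxcl3 at 5.32 ± 0.57, Rcl1 at 4.80 ± 0.42 and Il6 at 3.44 ± 0.73, and the mitochondrial transfer RNA mt-Ty at 13.00 ± 3.05. Il6 did not pass with a pseudocount of 0.1 (3.28), nor mt-Ty with both controls as 1 group (8.65). Much of the mt-Ty value rests on the lone 6 h control library, as do its decreases with LPS alone and Poly I:C alone. Inflammatory cytokines gave 7 higher and 5 lower of 20 (7 and 6 adjusted over the list alone, camera adjusted p = 0.329, and adjusted p = 0.71 with an estimated correlation). Tnf did not pass, at 1.55 ± 0.75, except with the 6 h libraries alone, at the same value (adjusted p = 0.0117). Cholesterol biosynthesis genes gave 15 higher and 0 lower of 21 (17 and 0 adjusted over the list alone, camera adjusted p = 2.24e-09, and adjusted p = 0.011 with an estimated correlation). For Sqle the LPS effect was -3.44 ± 0.16 after PBS and -0.88 ± 0.13 after Poly I:C. Poly I:C alone had already lowered most of the cholesterol biosynthesis genes at 6 h. In all, the interaction was positive for 1524 genes and negative for 2001, and the LPS effect was smaller in size after Poly I:C for 891 and 1267 of these.

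Genes induced by LPS alone at one time were then followed at the other time in the comparison of Poly I:C with PBS before LPS. Of 1711 genes induced at least 2-fold at 6 h, 1238 were higher with Poly I:C at 2 h, 131 were lower and 342 did not pass (camera p = 1.70e-27, and p = 0.0157 with an estimated correlation). Of 653 genes induced at least 2-fold at 2 h, 296 were higher at 6 h, 122 were lower and 235 did not pass (camera p = 5.07e-06, and p = 0.256 with an estimated correlation). Each list was chosen in libraries of the other time. The lists come from this study's own samples and are not independent evidence of direction.

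Other lists completed the comparison of Poly I:C with PBS before LPS. At 2 h immediate-early genes gave 11 higher and 1 lower of 17 (11 and 1 adjusted over the list alone, camera adjusted p = 0.00295, and adjusted p = 0.299 with an estimated correlation). Egr1 changed by 3.44 ± 0.19. Resident and alternative macrophage genes gave 4 higher and 12 lower of 22 (4 and 12 adjusted over the list alone, camera adjusted p = 0.00218, and adjusted p = 0.0786 with an estimated correlation). Cholesterol efflux genes gave 5 higher and 1 lower of 8 (5 and 1 adjusted over the list alone, camera adjusted p = 0.134, and adjusted p = 0.255 with an estimated correlation). Negative regulators of TLR signalling gave 9 higher and 6 lower of 20 (10 and 6 adjusted over the list alone, camera adjusted p = 0.327, and adjusted p = 0.705 with an estimated correlation). NF-kB subunits gave 3 higher and 0 lower of 4 (3 and 0 adjusted over the list alone, camera adjusted p = 0.185, and adjusted p = 0.536 with an estimated correlation). At 6 h the type I interferon and receptor genes gave 2 higher and 1 lower of 6 (3 and 1 adjusted over the list alone, camera adjusted p = 0.511, and adjusted p = 0.733 with an estimated correlation). Guanylate-binding proteins gave 2 higher and 3 lower of 9 (2 and 3 adjusted over the list alone, camera adjusted p = 0.905, and adjusted p = 0.95 with an estimated correlation). The inflammasome and cell death list gave 4 higher and 8 lower of 15 (4 and 9 adjusted over the list alone, camera adjusted p = 0.18, and adjusted p = 0.781 with an estimated correlation). The effectors gave 7 higher and 6 lower of 21 (7 and 6 adjusted over the list alone, camera adjusted p = 0.511, and adjusted p = 0.834 with an estimated correlation). Markers of other cells were few among the tested genes. At 2 h neutrophil markers gave 1 higher and 1 lower of 3 (1 and 1 adjusted over the list alone), with Csf3r at 3.33 ± 0.18 and S100a8 at -1.34 ± 0.24, and dendritic cell markers 2 higher and 0 lower of 4 (2 and 0 adjusted over the list alone), with Ccr7 at 3.27 ± 0.18. The T and NK cell list held Cd4 alone at 1.12 ± 0.21, the B cell list Cd22 alone at 1.01 ± 0.16, and the erythroid and mast cell list 0 tested genes. Of the replication histones, 2 were tested and Hist1h2bc was higher by 2.08, and 0 of the listed mitochondrially encoded genes had a tested entry of its own. At 6 h neutrophil markers gave 2 higher and 0 lower of 3 (2 and 0 adjusted over the list alone), with S100a8 higher by 1.61 ± 0.24, opposite to 2 h. Dendritic cell markers gave 1 higher and 0 lower of 4 (1 and 0 adjusted over the list alone), with Ccr7 at 3.83 ± 0.18, and the stromal list 2 higher and 0 lower of 8 (2 and 0 adjusted over the list alone), with Dcn at 2.11 ± 0.27. Cd4 and Cd22 did not pass, at 0.45 ± 0.21 and -0.07 ± 0.16, but Cd4 passed without Poly I:C-then-LPS replicate 2 (0.70). Hist1h2bc was higher by 2.24. The mitochondrial locus held 0.708% and 0.702% of named FPKM in the Poly I:C-then-LPS libraries at 6 h and 2.09% and 1.81% in the PBS-then-LPS libraries.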

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

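Both tests of the unnamed loci were chosen after the result was seen. The Poly I:C effect on the level after LPS was tested for a difference between 6 h and 2 h, and 2282 genes had a higher and 3030 a lower value at 6 h (limma, n = 2 libraries per group). Among named genes past that test, the difference on the log2 scale was -7.84 for Ms4a4c, -6.41 for the short RNA Gm23487, -6.35 for Slfn4, -4.91 for Irf7, -4.81 for Slfn1, -4.71 for Tlr3, -4.35 for Ccnd1, -3.88 for Ly6a, -3.72 for Nos2, -3.61 for Isg15, -3.55 for Ccl5 and -3.01 for Irg1. It was -2.44 for Tlr4, -2.43 for Arg1, -2.42 for Il10, -1.95 for Ptgs2, -1.69 for Cxcl10, -1.17 for H2-Q6, -1.06 for Slc16a3 and -0.91 for Slc2a1. Arg1 was at or near 0 FPKM in the 2 h libraries compared. A positive difference, which can be a less negative effect at 6 h, was found for Mrc1 at 0.83, Hk2 at 1.32, Il12b at 1.57, Cdca3 at 1.90, Igfbp4 at 2.55, Cxcl1 at 2.61, Cxcl3 at 3.75 and the short RNA DLEU2_5 at 10.60. DLEU2_5 kept its call in 1 of 8 fits that left out a library, that without PBS-then-LPS 2 h replicate 2, and lost it without the filter. Without PBS-then-LPS 2 h replicate 1 its value was 6.58, and without each of the other 6 libraries 10.15 to 11.04. Il12b did not pass with a pseudocount of 0.1 (1.60).

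Loci without a gene name were in no comparison, and many were higher with Poly I:C first. Of 963 tested, 654 were higher and 29 lower for Poly I:C against PBS before LPS at 2 h, 368 and 41 at 6 h, and for Poly I:C against PBS before PBS 317 and 12 at 2 h and 109 and 11 at 6 h. LPS against PBS gave 17 higher and 4 lower at 2 h and 96 and 20 at 6 h after PBS, and 401 and 45 at 2 h and 330 and 81 at 6 h after Poly I:C.

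Read-through from induced neighbours would make loci far from genes less often higher. Over 50 kb from any tested gene 71.5% of 186 loci were higher in the 2 h comparison before LPS, against 66.4% of 547 within 10 kb, a ratio of 1.08, which argues against read-through as the whole cause. Near loci were higher in 80.2% of 329 cases beside a gene called higher and in 45.4% of 218 otherwise, so read-through may add to part of them. More genomic DNA background would shift other named loci of like abundance too. The median of 1242 entries whose symbol is not protein-coding in GENCODE M21 was 0.22 against 1.15, a ratio of 0.189 (bootstrap 0.127 to 0.241). Protein-coding genes under older symbols can be among these entries, so the ratio does not settle the part of DNA background. Transcription of these loci with Poly I:C stays open as a hypothesis beside DNA background, and how Cufflinks assembled them was not tested.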

How the results depend on the processing

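Of the alternatives below, the restriction to protein-coding entries and the merged list members were chosen after the data had been seen. Of 296 counts under alternatives, 273 lay within 1.5 times the reported count, including all those with median-of-ratios scaling, a replicate term, no filter or no intensity trend. The 23 others belong to the 2 h comparisons of LPS with PBS and to the 2 h interaction. For LPS after PBS at 2 h the counts higher and lower were 747 and 429 with the 2 h libraries alone, 1720 and 1153 with both PBS-then-PBS libraries as 1 control group, and 1132 to 2296 and 661 to 1407 when a replicate was left out. For LPS after Poly I:C at 2 h they were 1094 to 1246 and 449 to 588 when a replicate was left out, and 609 lower with the 2 h libraries alone. For the 2 h interaction they were 109 and 86 with the 2 h libraries alone, 184 higher with a pseudocount of 0.1, and 146 to 836 and 129 to 801 when a replicate was left out. The highest counts for LPS after PBS and for the interaction came without PBS-then-LPS 2 h replicate 2. That pair agreed least, with an SD of 0.505 for the log2 difference between replicates and 306 genes over 2-fold apart. The other groups had 0.326 to 0.404 and 95 to 217 genes. A replicate left out also leaves fewer libraries, and the cause was not tested. Of 4480 values for named genes, 4297 kept their side of the threshold, 149 passed no longer and 34 passed newly. Direction reversed in 0 values of genes that passed in either fit. A change of sign in a gene that passed in neither fit was not counted. The median of all genes moved by -0.031 to 0.047 with median-of-ratios scaling. The deposited values were already centred, with factors of 0.99 to 1.04, so this rescaling could change little and is a weak test of scaling. The lone PBS-then-PBS library of each time, and any group left with 1 library, is assumed to vary like the other groups. With a replicate term, Poly I:C against PBS before LPS gave 3827 higher and 3330 lower at 2 h and 2704 and 2976 at 6 h. Low FPKM values rest on few fragments of unknown number, which limits the short RNAs above all.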

Other observations

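The gene lists and their tests were fixed before the data were examined. Of the tests of explanations below, those on genes matched for abundance and for GC content and length were fixed before their results were seen, and all others were chosen after. Amino-acid and ER stress genes went both ways with Poly I:C before LPS at 2 h, 10 higher and 4 lower of 17 (10 and 4 adjusted over the list alone, camera adjusted p = 0.0572, and adjusted p = 0.321 with an estimated correlation). Ddit3, encoding the stress-induced factor CHOP, changed by 5.24 ± 0.20, Trib3 by 4.35 ± 0.11, Sesn2 by 2.98 ± 0.12 and Sdf2l1 by -3.08 ± 0.19 (n = 2 libraries per group). At 6 h the list gave 11 higher and 4 lower of 17 (11 and 4 adjusted over the list alone, camera adjusted p = 0.039, and adjusted p = 0.459 with an estimated correlation). Of the cholesterol efflux genes at 2 h, the transporter gene Abcg1 changed by 3.08 ± 0.13, Ch25h, which makes an oxysterol, by 2.82 ± 0.30, and the lipoprotein lipase gene Lpl by -2.75 ± 0.19. In the stromal list Dcn changed by 3.13 ± 0.27, Col1a2 by 1.97 ± 0.54, Sparc by 1.80 ± 0.53 and Col1a1 by 1.60 ± 0.56. Without Poly I:C-then-LPS replicate 1, Col1a2, Sparc and Col1a1 did not pass, at 1.17, 1.00 and 0.79. Sparc also did not pass without PBS-then-LPS replicate 2 (1.72), nor Col1a1 without PBS-then-LPS replicate 1 (1.64) or 2 (1.56), and neither passed without the filter, at the same values (adjusted p = 0.0518 and 0.0928).

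In the Poly I:C-then-PBS group at 2 h, replicate 1 held more inflammatory transcript than replicate 2, with Tnf at 285 and 71.5 FPKM. RNA of the Poly I:C-then-LPS libraries mixed into replicate 1 would add the same share of every LPS-induced gene. Over 17 genes at least 50 times higher after LPS than in replicate 2, of which 16 were higher in replicate 1, the implied share ran from 0.302% to 5.58% between the 10th and 90th percentiles, a ratio of 18.5, which argues against mixing as the whole cause. The limit of 50 times replaced one of 10 times after a run whose outcome was the same. No biological explanation was tested, since nothing in the labels tells the replicates apart.

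Most glycolysis genes were lower with Poly I:C before LPS at 2 h, with a list median of -0.95 (camera adjusted p = 1.65e-04, and adjusted p = 0.196 with an estimated correlation). Scaling, or a few abundant genes taking more of the total, would lower all genes alike. The median of all genes was 0.054, a difference of 1.01, but the deposited values were already centred between libraries, with median-of-ratios factors of 0.99 to 1.04, which holds this median near 0. A lower level of these genes cannot be told apart from a rise of most other genes. An abundance trend would lower other abundant genes, but the list lay at percentile 0.01 of 10000 random lists matched on mean FPKM. Their 2.5th percentile was -0.39, and not every random list lay above the glycolysis list. A trend with GC content and length was weighed in lists matched on both, with the same percentile, 0.01, and a 2.5th percentile of -0.41, and 20 of 20 members had a GC value. The matched lists argue against both trends as the whole cause. The matched lists had medians of 0.15 and -3.2e-04, which argues against scaling for the lower level relative to other genes. Scaling leaves the absolute level of these genes open, and an effect of the earlier Poly I:C on them stays open as well.

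The 2 stimuli may simply add on the FPKM scale, and the measured level after both was set against the sum of the separate effects. For interferon-stimulated genes at 2 h the median log2 ratio was 0.22 (bootstrap 0.0837 to 0.341), within the bound of 0.5 set for adding. In both libraries 19 of 28 genes lay above the sum and 6 below. Where Poly I:C alone makes up most of the sum, a ratio near 0 cannot tell adding from no further LPS effect. For Irf7 the sum was 3148 FPKM, and the Poly I:C-then-PBS libraries alone held 2984 and 3182. The result at 2 h therefore does not show adding. At 6 h the median log2 ratio was -0.78 (-0.94 to -0.55), with 28 of 28 below, which argues against adding at that time. For inflammatory cytokines it was 1.15 at 2 h (0.435 to 2.01) and 1.16 at 6 h (0.386 to 2.30), with 17 and 15 of 20 above the sum and 3 and 4 below. In 13 genes at 2 h and 12 at 6 h both libraries lay over 0.5 log2 above a sum taken from the highest replicates, which argues against adding for most of this list, while 1 and 3 lay as far below a sum from the lowest. Tnf at 2 h stood at 5856 FPKM against a sum of 791. For the interferon-stimulated genes at 2 h, 2 lay that far above and 1 below. The bootstrap rule was added with the tests and resampled the genes of a list, not libraries, and 1 control library stands behind each sum.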
